A study of Mus musculus with 24 samples.

How the data were processed

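RNA sequencing was deposited for mouse lung basal cell derived organoids, lung squamous cell carcinoma cell lines and lung squamous cell carcinoma tumors. The series holds 24 samples. The 14 RNA libraries with count tables were used, and the 10 samples of chromatin accessibility and histone marks, which came without a table of counts, were not analysed here. Genotypes are given as the labels state them: P is Trp53-/-, PP is Trp53-/-; Pten-/- and P2D is Trp53-/-; Kmt2d-/-. The organoid groups P and P2D held 2 libraries each, the cell line groups PP and P2D held 2 libraries each from 1 line per genotype, and the tumor groups PP and P2D held 3 libraries each.

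Libraries were polyA selected and stranded, per the labels. The deposited tables hold expected counts per gene, 1 column per library, not scaled to library size. Per the submitters' processing notes, FastQC, STAR and RSEM were used with the mouse build mm10, and no tool versions or annotation release were given. Each of the 3 tables held 55487 genes, of which 54349 identifiers were found in the reference gene names, and 234 names were shared by several identifiers. Between 9.9% and 12.1% of the values of a library were not whole numbers, as RSEM divides reads between genes, and the expected counts were rounded to whole numbers for the tests. In the cell line table both P2D columns carry the same replicate number, so these libraries are called a and b, and which of them is the label's replicate 1 is not known.

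Genes were kept with edgeR's filterByExpr in each setting, scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, with the package's default legacy fit) in R 4.3.3. Each setting had its own fit with the genotype group alone. P-values were two-sided and adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called. Levels are CPM with TMM scaling, given as mean ± SD, and fold changes are log2 values of P2D over the reference. The difference between the tumor effect and the cell line effect was tested as a contrast of the 4 group means in a joint fit. Overlaps between settings were tested with a one-sided hypergeometric test for more shared genes than independent calls would give, adjusted over the 12 pairs of settings and directions.

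Before the data were examined, 47 gene lists with 1120 genes were fixed, of which 1119 were found in the tables. Lists with at least 3 tested members were tested with limma 3.58.1 camera on voom values, with the correlation between genes preset at 0.01, and adjusted over the lists of the setting. The same test was run with an estimated correlation, on ranks and with fry. With an estimated correlation 0 lists were called in any setting, also where the estimate was below the preset value. The comparisons, the tests, the naming rule and most alternatives were also fixed before the data were examined. The rule names Kmt2d, Trp53 and Pten always. It names the 10 largest changes in each direction among called genes with at least 20 CPM in the higher group, no overlap between the groups' libraries and no predicted-gene style name. It names members of the called lists and of 6 central lists, with up to 4 in the leading direction and 2 in the other, by adjusted p and with at least 5 CPM in the higher group. Where no member passed, it names the 2 members with the highest level. For effects that differ between tumors and cell lines it names the 5 largest in each direction. Egfr, organoid Hmga2, Mid1-ps1, the lung tissue transcripts, Gpx2 in the cell lines, and Plat and Irx2 in organoids and cell lines were chosen after their values were seen.

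The procedure was tested on simulated data with known changes in 200 genes, once with each gene's own estimated spread and once with the spread trended over expression. With each gene's own spread, 2-fold changes were recovered for 82.9% of genes in the organoid design, 83.3% in the cell line design and 0% in the tumor design, and 4-fold changes for 97%, 95.9% and 43.1%. In the same simulations 12.4%, 13.3% and 24.2% of the calls were false, and with trended spread 5.5%, 4.5% and 1.8%. The share of false calls depends on how many genes change. With only 200 changed genes it does not carry over to the larger counts in organoids and cell lines. For the difference between tumors and cell lines, 31.5% of the 4-fold differences were recovered and 7.4% of the calls were false. That simulation gave cell lines and tumors the same spread for each gene. In the data tumors varied more, so these 2 shares do not carry over to that test. A list shifted by 0.5 log2 was called in each setting, and 0 of the 44, 43 and 45 other lists were called. These simulated genes varied independently, so the list simulation does not cover correlation between genes.

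Alternatives covered scaling (DESeq2 style size factors, library size only, upper quartile), the filter on low counts, the test (DESeq2 1.42.0, limma voom, edgeR without the legacy or robust options), rounding, thresholds, 1 fit over all settings, replicate number as a block, a leukocyte covariate in tumors, and leaving out each library in turn. In the organoid and cell line fits this leaves 1 library in a group. The other group alone then gives the spread, and calls from such fits are weak evidence of stability. Folds against a group with 0 counts were set against a floor of 3 counts over the group, and ratios with 1 to 3 counts carry an exact 95% binomial interval that covers counting error only. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, version 1.17.8 of data.table was used in R, and plots were drawn with matplotlib 3.10.9. The labels do not state whether replicates came from separate animals or cultures, so the p-values measure the spread between these libraries.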

Results

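Gene expression was measured by RNA sequencing in 14 libraries from mouse lung squamous models that lack Trp53. There were 4 libraries of basal cell derived organoids (2 labelled P and 2 labelled P2D), 4 of squamous carcinoma cell lines (2 PP and 2 P2D) and 6 of squamous tumors (3 PP and 3 P2D). P2D libraries are labelled as lacking Kmt2d, which encodes a histone H3K4 methyltransferase. The organoid libraries held 36048349 to 44338631 expected counts, the cell line libraries 37953455 to 45096880 and the tumor libraries 27315614 to 35549119. The first principal component separated the genotypes in each setting, with 75.6% of the variance in organoids, 91.9% in cell lines and 40.8% in tumors.

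The targeted genes were Kmt2d (ENSMUSG00000048154.17, chromosome 15, 98831669 to 98874077, build mm10), Trp53 (ENSMUSG00000059552.13, chromosome 11, 69580348 to 69591873) and Pten (ENSMUSG00000013663.7, chromosome 19, 32757577 to 32826160). Kmt2d transcript was not lower in libraries labelled P2D. In organoids it was at 94.6 ± 6.63 CPM (SD, n = 2) in P2D and 71.5 ± 3.05 in P, a rise of 0.40 log2 (adjusted p = 4.72e-07). In cell lines it was at 102 ± 20.6 and 64.6 ± 8.87 CPM (adjusted p = 0.137, while DESeq2 and limma voom called it higher at 0.0182 and 0.000536), and in tumors at 67.4 ± 23.2 and 32.3 ± 17.3 CPM (adjusted p = 0.272). Counts per gene also cover the exons outside a deletion, so these values do not check the genotype. Trp53 was low in the cultures, at 1.56 and 0.821 CPM in P2D and P organoids and at 2.47 and 3.57 CPM in P2D and PP lines, and was at 5.76 and 6.46 CPM in P2D and PP tumors. Pten was at 126 ± 0.769 CPM in the P2D line and 96.2 ± 2.36 in the PP line (adjusted p = 1.13e-07), and at 107 ± 17 and 104 ± 10.8 CPM in P2D and PP tumors (adjusted p = 0.928).

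The organoid comparison asks what Kmt2d deletion changes in Trp53-deleted basal cells, since by the labels the groups differ in Kmt2d alone. Whether the replicates came from separate cultures is not stated, so other differences between the cultures are not excluded. The biological coefficient of variation was 0.049 here, near the 0.0421 of the single cell lines and below the 0.4 of tumors. Genes of squamous differentiation and interferon-stimulated genes were higher in P2D organoids, and genes of the cell cycle, DNA replication and cholesterol synthesis were lower. These list calls were made with the preset correlation and were lost with an estimated one (adjusted p from 0.446 to 0.562). Krt13, a keratin of differentiating stratified epithelium, was at 1020 ± 55.9 CPM (SD, n = 2) in P2D and 136 ± 12.2 in P. Krt15, a keratin of basal cells, was at 804 ± 17.7 and 216 ± 6.3 CPM. Pcsk9, which directs the LDL receptor to degradation, was at 90.6 ± 3.93 CPM in P2D and 273 ± 4.65 in P. The largest rises by the naming rule were in Wfdc18, Calm4, Flg, Krt79, Krt6b, Atf3, Nccrp1, Igfbp5, Krt13 and Vim, with log2 changes from 5.59 for Wfdc18 to 2.83 for Vim. The largest falls were in Padi3, Ccl11, Pcolce, Nexn, Slc7a11, Thbs2, Thsd4, Agr2, Gpm6b and Slc4a11, with log2 changes from -3.05 for Padi3 to -2.05 for Slc4a11.

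Of the 33 tested members of the squamous terminal differentiation list, 25 rose and 5 fell in P2D organoids (camera adjusted p = 8.79e-09, and adjusted p = 0.447 with an estimated correlation). Filaggrin (Flg) rose by 4.19 log2, Calml3 by 2.16 and cornulin (Crnn) by 1.67, while the transglutaminase Tgm1 fell by 0.92. The basal squamous identity list had 20 of 32 members higher and 6 lower (adjusted p = 0.000698, and adjusted p = 0.749 with an estimated correlation). In it Krt6a rose by 1.30 log2 and the receptor gene Ngfr fell by 0.83. Of 35 interferon-stimulated genes, 32 rose and 2 fell (adjusted p = 9.96e-16, and adjusted p = 0.446 with an estimated correlation). Ifit3 rose by 2.36 log2 and Ifit1 by 1.82, while Mx1 fell by 0.89. Genes of class I antigen presentation rose in 12 of 20 cases and fell in 3 (adjusted p = 0.00548, and adjusted p = 0.766 with an estimated correlation), with Tap1 up by 1.11 log2 and B2m by 0.65.

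All 29 tested G2M genes fell in P2D organoids (adjusted p = 2.59e-15, and adjusted p = 0.562 with an estimated correlation), as did 33 of 35 genes of DNA replication and E2F targets (adjusted p = 1.67e-16, and adjusted p = 0.446 with an estimated correlation). Log2 changes were -0.94 for the mitotic kinase gene Cdk1, -0.85 for Top2a, -1.10 for Rrm2, a subunit of ribonucleotide reductase, and -0.97 for the helicase subunit Mcm5. Cholesterol synthesis genes fell in 22 of 24 cases (adjusted p = 4.18e-11, and adjusted p = 0.447 with an estimated correlation), among them Hmgcr, the rate-limiting enzyme, with a log2 change of -0.76. In the unfolded protein and amino acid stress list 20 of 27 members fell and 4 rose (adjusted p = 1.27e-05, and adjusted p = 0.696 with an estimated correlation), with log2 changes of -1.57 for the serine synthesis gene Psat1, -1.33 for asparagine synthetase (Asns) and 3.81 for Atf3. NRF2 targets fell in 16 of 28 cases and rose in 5 (adjusted p = 0.00661, and adjusted p = 0.766 with an estimated correlation), with log2 changes of -1.24 and -1.12 for the glutathione genes Gclm and Gpx2. Oxidative phosphorylation genes fell in 20 of 35 cases (adjusted p = 0.00549, and adjusted p = 0.847 with an estimated correlation), with Uqcrq at -0.30 log2. Without P replicate 2 this list was no longer called (adjusted p = 0.387). Mitochondrially encoded genes fell in 10 of 15 cases and rose in 2 (adjusted p = 0.00912, and adjusted p = 0.766 with an estimated correlation), with mt-Cytb at -0.59 and mt-Rnr2 at 0.59 log2. These genes took 1.2% to 1.25% of the counts in P2D libraries and 1.58% to 1.8% in P libraries.

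Among signalling genes, 17 of 34 receptor tyrosine kinase genes rose and 5 fell in P2D organoids, and 19 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0126, and adjusted p = 0.766 with an estimated correlation). This call ended without P replicate 2 (adjusted p = 0.14) and with replicate number as a block (adjusted p = 0.0633). Ephb3 rose by 0.68 log2 and Fgfr2 by 0.54, and Axl fell by 0.86. Egfr, chosen after its values were seen, was at 180 ± 1.46 CPM in P2D and 132 ± 6.45 in P (adjusted p = 5.62e-09). Transcripts that follow ERK activity fell in 13 of 23 cases and rose in 5, or 6 adjusted over the list alone (adjusted p = 0.0267, and adjusted p = 0.766 with an estimated correlation). On ranks the adjusted p was 0.0628. Log2 changes were -1.78, -1.57 and -1.24 for the ETS factor genes Etv1, Etv5 and Etv4, and the phosphatase gene Dusp5 rose by 1.51. Hmga2, also in this list and chosen after its values were seen, was at 65.6 ± 1.16 CPM in P2D and 109 ± 3.99 in P (adjusted p = 1.14e-14). Of 9 EGFR family ligands 5 fell and 1 rose, and the list was not called (adjusted p = 0.116). Areg fell by 0.64, Nrg1 fell by 0.48, and Hbegf rose by 0.62. Receptor protein tyrosine phosphatases, which remove phosphate from tyrosine, went both ways, with 5 of 12 higher and 3 lower (adjusted p = 0.368). Ptpru rose by 2.02 and Ptprd by 1.00, and Ptprz1 fell by 0.73.

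Hypoxia and glycolysis genes rose in 19 of 32 cases and fell in 3 (adjusted p = 0.00133, and adjusted p = 0.766 with an estimated correlation), with Ndrg1 up by 1.51 log2 and Bnip3 by 0.77. YAP and TEAD targets rose in 14 of 25 cases and fell in 6 (adjusted p = 0.00607, and adjusted p = 0.749 with an estimated correlation), with Ccn1 up by 1.21 and Ccn2 by 1.11. Immediate early genes rose in 12 of 21 cases and fell in 6 (adjusted p = 0.000698, and adjusted p = 0.766 with an estimated correlation), with Klf6 up by 1.76 and Jun by 1.65. Across all 14614 tested genes, 3607 were higher and 3728 lower in P2D organoids by edgeR, of which 650 and 550 changed at least 2-fold. In simulations of this design with 200 changed genes, 12.4% of calls were false with each gene's own spread and 5.5% with trended spread. Far more genes were called in the data, so these shares do not carry over to the counts. In 1 fit over all settings, which shares its spread with the more variable tumors, the counts were 100 and 81.

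The cell line comparison sets 1 P2D line against 1 PP line, so Kmt2d, Pten and everything else that differs between the lines cannot be told apart in it. Transcripts of ERK output and EGFR ligands were higher in the P2D line, and genes of squamous differentiation and of fibroblast type matrix were lower. These list calls were made with the preset correlation and were lost with an estimated one (adjusted p from 0.425 to 0.638), and that of the EGFR ligands, of which 7 of 10 rose and 2 fell, was also lost on ranks (0.0755). Hmga2, an architectural chromatin protein gene, was at 96.3 ± 5.38 CPM (SD, n = 2) in P2D and 1.56 ± 0.0694 in PP. The integrin gene Itga2 was at 245 ± 13.8 and 2.98 ± 0.139 CPM. Spink5, a protease inhibitor of differentiating epithelium, was at 42.2 ± 4.18 CPM in P2D and 1700 ± 24.5 in PP. Other large rises by the naming rule were in Glrp1, Cdh6, Fosl1, Sema7a, Plac8, Adgrl3, Itgb7 and Stc2, with log2 changes from 5.70 for Glrp1 to 4.57 for Stc2. Several of the largest falls were in genes close to absence in the P2D line. Cntn2 had 2 counts there (3380-fold lower, 95% counting interval 935 to 27900), Postn 2 (1590-fold lower, 440 to 13200), Col1a2 1 (1790-fold lower, 321 to 70900) and Htra4 2 (1240-fold lower, 343 to 10200). Log2 changes were -9.12 for Igfbp2, -9.06 for Col5a1 and -9.04 for Ctnnd2.

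Of 24 tested transcripts of ERK pathway output, 19 rose and 3 fell in the P2D line (camera adjusted p = 1.07e-05, and adjusted p = 0.425 with an estimated correlation). Fosl1 rose by 5.18 log2, Etv5 by 2.70 and Phlda1 by 1.72, while Egr1 fell by 1.52. EGFR family ligands rose in 7 of 10 cases and fell in 2 (adjusted p = 0.0405, and adjusted p = 0.638 with an estimated correlation), and the adjusted p on ranks was 0.0755. Epiregulin (Ereg) rose by 3.94 and amphiregulin (Areg) by 3.60, while Epgn fell by 4.58. Receptor tyrosine kinase genes went both ways, with 14 of 38 higher and 19 lower (adjusted p = 0.417). Axl rose by 2.22 and Fgfr2 fell by 2.20, and Egfr, chosen after its values were seen, was at 84.9 ± 3.27 CPM in P2D and 70.3 ± 3.1 in PP (adjusted p = 0.000103). Receptor protein tyrosine phosphatases were 4 of 11 higher and 5 lower (adjusted p = 0.82), with log2 changes of 2.80 for Ptprg, -4.94 for Ptpru and -0.76 for Ptprf.

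Squamous terminal differentiation genes fell in 30 of 33 cases and rose in 2 in the P2D line (adjusted p = 2.72e-09, and adjusted p = 0.425 with an estimated correlation). Calml3 fell by 3.54 log2, and Scel, another gene of the cornified envelope, rose by 1.82. In the basal squamous identity list 23 of 32 members fell and 8 rose (adjusted p = 0.00247, and adjusted p = 0.502 with an estimated correlation), with log2 changes of -3.42 for the desmosomal gene Dsc3, -3.15 for Krt15 and 4.08 for Ngfr. Mesenchymal genes fell in 18 of 26 cases and rose in 5 (adjusted p = 0.00506, and adjusted p = 0.425 with an estimated correlation), with log2 changes of -6.82 for Fstl1 and 2.63 for Thbs2. Of 18 fibroblast genes, 15 fell and 1 rose (adjusted p = 3.34e-06, and adjusted p = 0.425 with an estimated correlation). Col1a1 fell by 8.46 and Igfbp5 fell by 5.28, and in the PP line these were at 200 ± 9.18 and 666 ± 21.8 CPM.

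Inflammatory cytokine genes rose in 15 of 26 cases and fell in 7 in the P2D line (adjusted p = 0.043, and adjusted p = 0.425 with an estimated correlation), with Il1a up by 4.43 log2 and Cxcl5 by 3.03, and on ranks this list was not called (adjusted p = 0.08). The unfolded protein and amino acid stress list rose in 23 of 27 cases and fell in 1 (adjusted p = 6.56e-09, and adjusted p = 0.425 with an estimated correlation), with cystathionine gamma-lyase (Cth) up by 3.78 and Trib3 by 2.96. Cholesterol synthesis genes rose in 18 of 24 cases and fell in 2 (adjusted p = 0.000294, and adjusted p = 0.425 with an estimated correlation), with Pcsk9 up by 3.45 and Sqle by 0.85. G2M genes rose in 20 of 29 cases and fell in 7 (adjusted p = 0.0161, and adjusted p = 0.425 with an estimated correlation), with log2 changes of 0.54 for Cdk1 and -0.37 for Mki67. YAP and TEAD targets rose in 15 of 24 cases and fell in 6 (adjusted p = 0.0339, and adjusted p = 0.425 with an estimated correlation), with Asap1 up by 2.08. Regulators of WNT fell in 14 of 20 cases and rose in 3 (adjusted p = 0.0151, and adjusted p = 0.425 with an estimated correlation), with log2 changes of -2.35 for Wnt11 and 2.18 for Lgr6, and without P2D library a it was not called (adjusted p = 0.0539). Hedgehog pathway genes fell in 7 of 9 cases and rose in 1 (adjusted p = 0.0186, and adjusted p = 0.569 with an estimated correlation), with Gli1 at -4.85 log2. Immediate early genes fell in 15 of 21 cases and rose in 6 (adjusted p = 0.0103, and adjusted p = 0.425 with an estimated correlation), with Jun at -1.40 log2.

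Mitochondrially encoded genes fell in 11 of 15 cases in the P2D line (adjusted p = 1.03e-05, and adjusted p = 0.578 with an estimated correlation), with log2 changes of -1.81 for mt-Rnr2 and -0.72 for mt-Cytb. They took 0.91% to 1.01% of the counts in P2D libraries and 1.7% to 1.76% in PP libraries. The 4 tested genes of the sex-chromosome list, all Y-linked, fell (adjusted p = 0.0064, and adjusted p = 0.425 with an estimated correlation): Eif2s3y was at 0.0537 ± 0.0374 CPM in P2D and 69.4 ± 2.33 in PP, Ddx3y and Kdm5d changed by -9.85 and -8.97 log2, and Uty had 2 counts in P2D (969-fold lower, 95% counting interval 268 to 8010). The other tested Y-linked gene, the pseudogene Mid1-ps1, chosen after its values were seen, was at 6.9 ± 0.885 CPM in P2D and 6.75 ± 0.211 in PP (adjusted p = 0.825). Median changes also differed between autosomes, from -0.417 log2 over 760 genes of chromosome 8 to 0.366 over 582 genes of chromosome 15, which carries Kmt2d. Across 14958 tested genes, 5185 were higher and 5212 lower in the P2D line by edgeR, of which 1102 and 1906 changed at least 2-fold. In simulations of this design with 200 changed genes, 13.3% of calls were false with each gene's own spread and 4.5% with trended spread. These shares do not carry over to the larger counts here. In 1 fit over all settings the counts were 1237 and 1392.

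**Figure D1:**
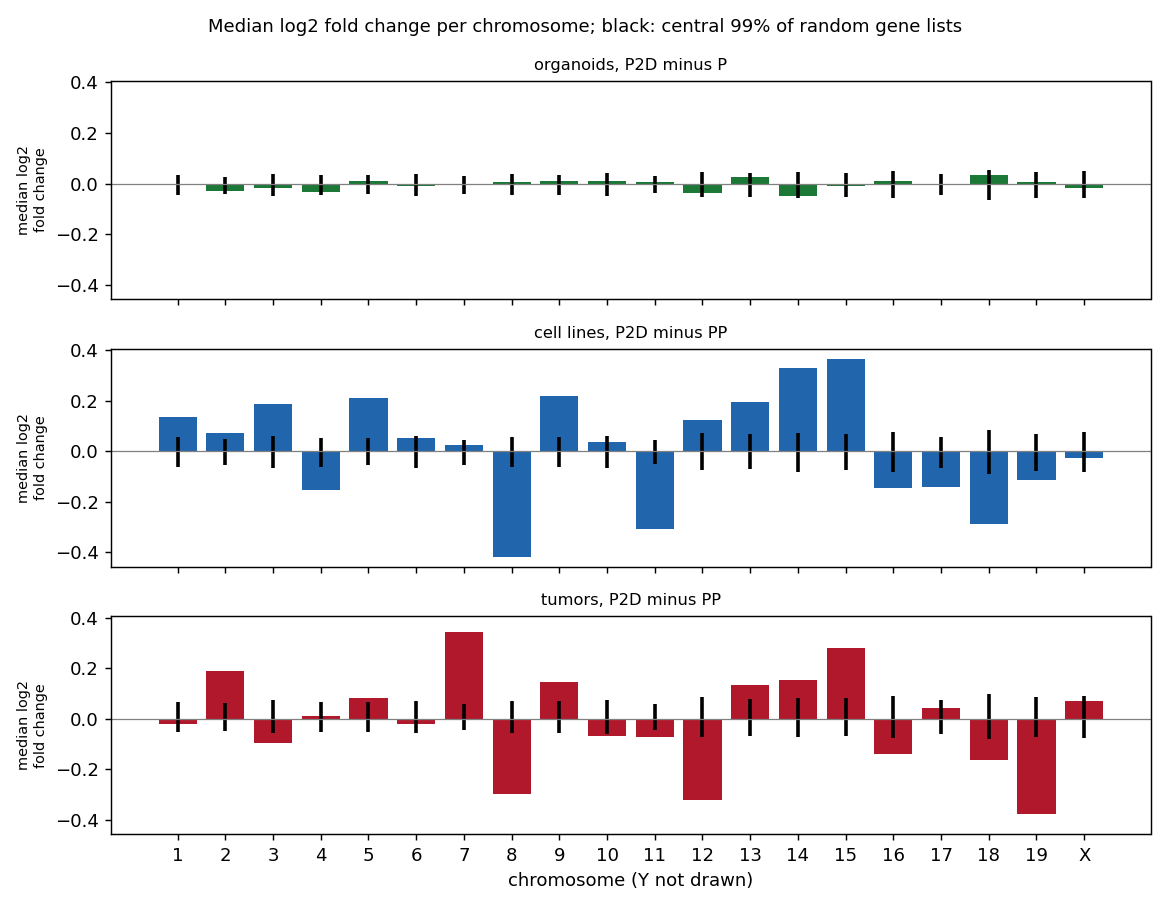
Median log2 fold change of the tested genes of each chromosome (bars) in organoids, cell lines and tumors, with the central 99% of random gene lists of the same size in black. Organoid chromosomes stay within the random range, while 16 autosomes in the cell lines and 15 in tumors lie outside it, such as chromosomes 8 (-0.417) and 15 (0.366) in the lines and 19 (-0.376) and 7 (0.344) in tumors.

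The tumor comparison sets P2D against PP squamous tumors, so by the labels the groups differ in Kmt2d and in Pten, and other differences between them are not excluded. Hmga2 and some other transcripts of ERK output (4 of 24 in all) were higher in P2D tumors, and some genes of neutrophils, macrophages, cholesterol synthesis and squamous differentiation were lower. The calls of these lists were lost with an estimated correlation (adjusted p from 0.536 to 0.745) and with fry. Hmga2 was at 25.2 ± 10.9 CPM (SD, n = 3) in P2D and 0.395 ± 0.341 in PP. Etv4 was at 18.4 ± 4.5 and 2.57 ± 1.08 CPM. Calml3 was at 772 ± 128 CPM in P2D and 2460 ± 312 in PP. The neutrophil gene S100a9 was at 14.7 ± 4.25 and 110 ± 27.1 CPM. Other large rises by the naming rule were in Sncg, Adgrl3, Slc16a11, Thbs2, Sostdc1, Irx2, Nlrp10, Rgma and Tanc2, with log2 changes from 4.04 for Sncg to 2.36 for Tanc2. The largest falls were in Myl7, Pcdhgb5, Add2, Gal3st4, Folr2, Eif2s3y, Kdm5d, Tnfrsf11b, Uty and Vgll3, from -6.80 for Myl7 to -3.72 for Vgll3.

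Of 24 ERK output transcripts 4 rose in P2D tumors over all genes tested, and 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 3.85e-06, and adjusted p = 0.536 with an estimated correlation). These were Hmga2, Etv4, Spry2 and Myc, with Spry2 up by 2.13 log2 and Myc by 1.07. The EGFR family ligand list was called higher with 3 of 9 members higher adjusted over the list alone (adjusted p = 0.00345, and adjusted p = 0.613 with an estimated correlation). None of its members passed over all genes tested in edgeR, while 4 had an unadjusted p under 0.05 and 3 were called by DESeq2. Its most abundant members did not pass the test, with Hbegf at 94.1 ± 50.5 and 76.3 ± 11.6 CPM (adjusted p = 0.669) and Tgfa at 80.1 ± 34.4 and 81.1 ± 26.3 CPM (adjusted p = 0.982). Of 42 receptor tyrosine kinase genes 1 rose, and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.198, and 0.0159 without PP replicate 1). That gene was Igf1r, at 93.2 ± 21.6 and 34 ± 8.08 CPM (adjusted p = 0.0402). Egfr, chosen after its values were seen, was at 79.1 ± 7.8 CPM in P2D and 60.3 ± 11.6 in PP (adjusted p = 0.357). Among 16 receptor protein tyrosine phosphatases Ptprz1 rose by 1.95, while 1 rose and 2 fell adjusted over the list alone and by DESeq2. The list was not called (adjusted p = 0.981, with a median of -0.01 against an upward test direction).

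Squamous terminal differentiation genes were lower as a list in P2D tumors (adjusted p = 8.61e-07, and adjusted p = 0.745 with an estimated correlation), with 2 of 37 members passing over all genes tested and 3 adjusted over the list alone. These 2 were Sprr2a1, which fell by 3.68 log2, and Calml3. The basal squamous identity list was not called (adjusted p = 0.171, and 0.0195 without PP replicate 1), and Krt14 was at 8070 ± 3450 and 8680 ± 2640 CPM and Krt6a at 10100 ± 5860 and 6100 ± 1600 CPM. Neutrophil genes fell in 4 of 20 cases, and in 11 adjusted over the list alone (adjusted p = 5.95e-09, and adjusted p = 0.536 with an estimated correlation), with S100a8 at -2.58 log2. Macrophage and monocyte genes fell in 3 of 29 cases, and in 12 adjusted over the list alone (adjusted p = 9.84e-08, and adjusted p = 0.595 with an estimated correlation), with log2 changes of -2.80 for the integrin gene Itgam and -1.41 for Tyrobp. The erythroid list was lower, with 0 of 5 members passing over all genes tested in edgeR, 5 adjusted over the list alone, 5 at an unadjusted p under 0.05 and 4 by DESeq2 (adjusted p = 0.000129, and adjusted p = 0.595 with an estimated correlation), and Hba-a2 was at 47.8 ± 18.8 and 124 ± 11.2 CPM. The muscle and fat list was lower, with 1 of 7 members and 3 adjusted over the list alone (adjusted p = 0.00337, and adjusted p = 0.536 with an estimated correlation; 0.0513 without P2D replicate 2), with Myl7, a cardiac muscle gene, at 0.778 ± 0.239 and 86.4 ± 45.6 CPM. Lung tissue transcripts, chosen after the data were seen, were present in both groups, with Sftpc, a surfactant gene of alveolar cells, at 898 ± 283 CPM in P2D and 1280 ± 881 in PP (adjusted p = 0.611).

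G2M genes rose as a list in P2D tumors, with 1 of 29 members passing over all genes tested and 20 adjusted over the list alone (adjusted p = 1.52e-11, and adjusted p = 0.613 with an estimated correlation). Genes of DNA replication rose with 2 of 35 members and 17 adjusted over the list alone (adjusted p = 1.37e-07, and adjusted p = 0.613 with an estimated correlation). Cdc20 rose by 1.10 log2 and Mcm2 by 1.04. Cholesterol synthesis genes fell in 3 of 24 cases and in 11 adjusted over the list alone (adjusted p = 3.3e-05, and adjusted p = 0.613 with an estimated correlation), with log2 changes of -1.68 for Mvd and -1.53 for Msmo1. The list of matrix metalloproteinases and the plasminogen system fell in 4 of 21 cases and in 5 adjusted over the list alone (adjusted p = 0.00337, and adjusted p = 0.709 with an estimated correlation), with log2 changes of -3.30 for tissue plasminogen activator (Plat) and -1.66 for Mmp12. That call ended without PP replicate 1 (adjusted p = 0.0742) and without P2D replicate 3 (0.0684). Hypoxia and glycolysis genes were lower as a list, with 2 of 32 lower and 1 higher, and 3 and 1 adjusted over the list alone (adjusted p = 0.0038, and adjusted p = 0.932 with an estimated correlation), with log2 changes of -1.53 for Pgam1 and 1.99 for Car12. NRF2 targets were lower as a list, with 1 of 28 lower and 1 higher, and 4 and 2 adjusted over the list alone (adjusted p = 0.0292, and adjusted p = 0.932 with an estimated correlation), with log2 changes of -1.33 for Gpx2 and 1.64 for Aldh3a1. Without PP replicate 3 neither the hypoxia list (adjusted p = 0.116) nor the NRF2 list (0.116) was called, and without P2D replicate 3 their adjusted p were 0.107 and 0.242. Of 5 tested sex-chromosome genes 4 fell (adjusted p = 5.32e-07, and adjusted p = 0.536 with an estimated correlation), with Ddx3y at 5.78 ± 0.838 and 65.4 ± 20.7 CPM. The interferon-stimulated list was called higher with a median of 1.28 log2, though 0 of 35 members passed in edgeR and only 1, which was lower, passed adjusted over the list alone, at an unadjusted p under 0.05 or by DESeq2 (camera adjusted p = 0.044, and adjusted p = 0.937 with an estimated correlation). The call ended without P2D replicate 2 (adjusted p = 0.126, with the opposite direction), without PP replicate 2 (0.23) and without PP replicate 3 (0.203). Irf7 was at 92.5 ± 104 and 91.6 ± 7.42 CPM and Stat1 at 101 ± 120 and 41.5 ± 20.4 CPM. KMT2 complex members were called higher as a list (adjusted p = 0.0431, and adjusted p = 0.653 with an estimated correlation), but 0 of 18 passed in edgeR, adjusted over the list alone or by DESeq2, and 4 were higher and 1 lower at an unadjusted p under 0.05. This call ended without PP replicate 1 (adjusted p = 0.0631), PP replicate 3 (0.073) or P2D replicate 3 (0.17). In this list Wdr82 was at 110 ± 11.5 and 64.9 ± 13.1 CPM and Ash2l at 72.2 ± 15.4 and 136 ± 46.2 CPM, and neither passed the test.

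Across 15760 tested genes, 93 were higher and 164 lower in P2D tumors by edgeR, all at least 2-fold, while 3089 had an unadjusted p under 0.05 and DESeq2 called 587 and 736. The counts were 1594 and 1634 in 1 fit over all settings, 7 and 27 at an adjusted p under 0.01, and 22 and 53 with an alveolar covariate chosen after seeing the data. Simulations of this design with each gene's own spread recovered 43.1% of 4-fold changes, and 24.2% of their calls were false. With trended spread these were 72.1% and 1.8%. Leaving out a library moved the counts to 12 and 40 without PP replicate 1, 10 and 37 without PP replicate 2, 13 and 44 without PP replicate 3, 30 and 60 without P2D replicate 1, 34 and 51 without P2D replicate 3, and 76 and 116 without P2D replicate 2. Among the 42 named tumor genes that were called, 26 lost their call without PP replicate 1, 24 without PP replicate 2, 23 without PP replicate 3, 21 without P2D replicate 1, 10 without P2D replicate 2 and 19 without P2D replicate 3. Splits of the 6 tumors that mixed the genotypes called up to 26 lists, against 16 for the genotypes.

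**Figure D2:**
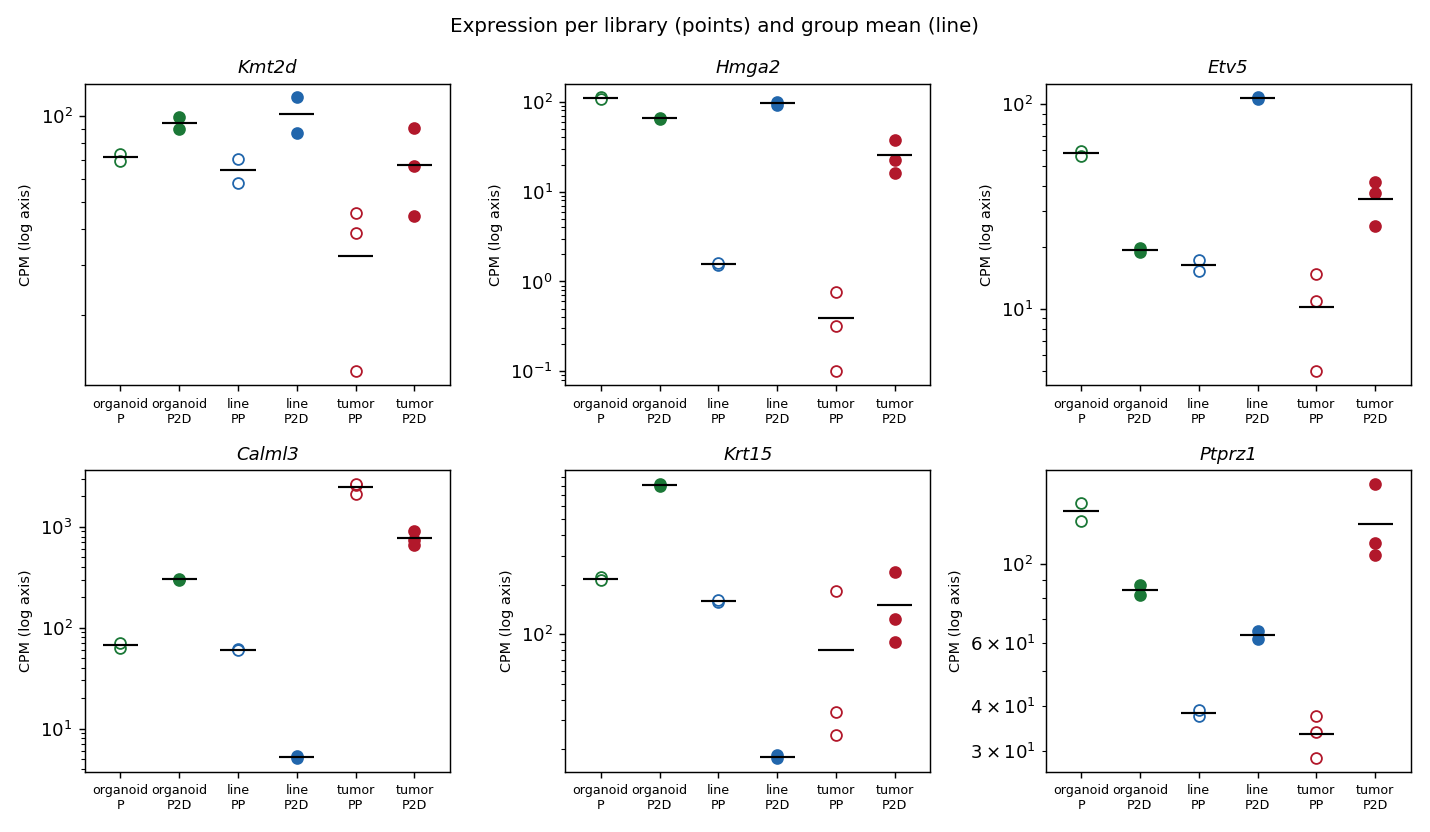
CPM of Kmt2d, Hmga2, Etv5, Calml3, Krt15 and Ptprz1 in each library (points, log axis), with group means as lines and open points for the reference genotype. Hmga2 is at 96.3 CPM in the P2D line and 25.2 in P2D tumors, above the reference of each, while in organoids it is at 65.6 CPM in P2D and 109 in P.

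The comparison of settings asks whether the P2D contrasts changed the same genes. The reference was P in organoids and PP in cell lines and tumors. Between organoids and the others, Kmt2d, Pten and the setting therefore cannot be told apart. Changes in tumors followed those in cell lines more than those in organoids. This ranking was not tested. The P2D line and tumors also shared lower Ddx3y, Eif2s3y, Kdm5d and Uty, and shifts of chromosomes 8 and 15 in the same direction. Whether line and tumors have a common origin was not tested, so their overlap need not be an independent repeat of the genotype effect. Hmga2 rose 61.4-fold in the P2D line and 64.1-fold in P2D tumors. Adgrl3 and Thbs2 rose by 4.65 and 2.63 log2 in the line and by 3.34 and 3.27 in tumors. Calml3 fell in both, and rose by 2.16 in organoids. Of the genes tested in both, 61 rose in lines and tumors where independent calls would give 32.5 (adjusted p = 2.95e-09), and 89 fell in both where 41.4 were expected (adjusted p = 1.25e-18). Organoids and lines more often changed in opposite directions. A total of 1646 genes fell in organoids and rose in lines where 1319.6 were expected (adjusted p = 6.66e-38), and 1344 rose in organoids and fell in lines where 1135.6 were expected (adjusted p = 1.23e-17). Those that rose in both were 1192 where 1258.2 were expected. At a 2-fold threshold, shared rises (59, adjusted p = 0.000244) and shared falls (99, adjusted p = 3.87e-17) were also more than expected, as were opposite changes (195, adjusted p = 3.94e-74, and 110, adjusted p = 4.01e-32). Between organoids and tumors, 38 genes fell in organoids and rose in tumors where 23.8 were expected (adjusted p = 0.00188), and 36 fell in both where 29.6 were expected (adjusted p = 0.204). At 2-fold these were 7 where 3 were expected (adjusted p = 0.0458) and 11 where 3.7 were expected (adjusted p = 0.00218). With DESeq2 calls the shared falls were not more than expected (108 where 116.2 were expected, adjusted p = 1), while 235 fell in organoids and rose in tumors where 123.1 were expected (adjusted p = 8.31e-27), and 150 rose in organoids and fell in tumors where 111 were expected (adjusted p = 5.26e-05, and 0.975 with edgeR calls). Pearson correlations across genes, which are not independent replicates, were 0.324 between lines and tumors, -0.15 between organoids and lines and -0.071 between organoids and tumors.

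The difference between the tumor effect and the cell line effect passed the test for 774 of 17430 genes, 496 with a higher and 278 with a lower effect in tumors. Of these, 447 had fitted values of opposite sign in the 2 settings. By the edgeR calls within each setting, only 11 genes were higher in lines and lower in tumors, and 21 the reverse. The joint fit shared 1 spread per gene between lines and tumors, whose biological coefficients of variation were 0.0421 and 0.4. Its p-values may therefore be too small where tumors varied more. Pdgfrb, a receptor of mesenchymal cells, had 0 counts in the P2D line, at least 334-fold lower than in the PP line, and was at 20.3 and 24.7 CPM in P2D and PP tumors (difference 11.55 log2, adjusted p = 0.000134). The cytokine genes Il1a and Cxcl5 rose by 4.43 and 3.03 log2 in the P2D line, and their effect was lower in tumors (differences -4.84 and -5.36, adjusted p = 0.0442 and 0.0286). Without 1 cell line library at a time the counts were 152 to 222 higher and 60 to 69 lower: 222 and 62 without PP replicate 1, 210 and 60 without PP replicate 2, 152 and 69 without P2D library a and 155 and 68 without P2D library b. Among the tumors, the lower count was 482 without P2D replicate 2 and 461 without P2D replicate 1, and the higher count was 752 without P2D replicate 2.

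**Figure D3:**
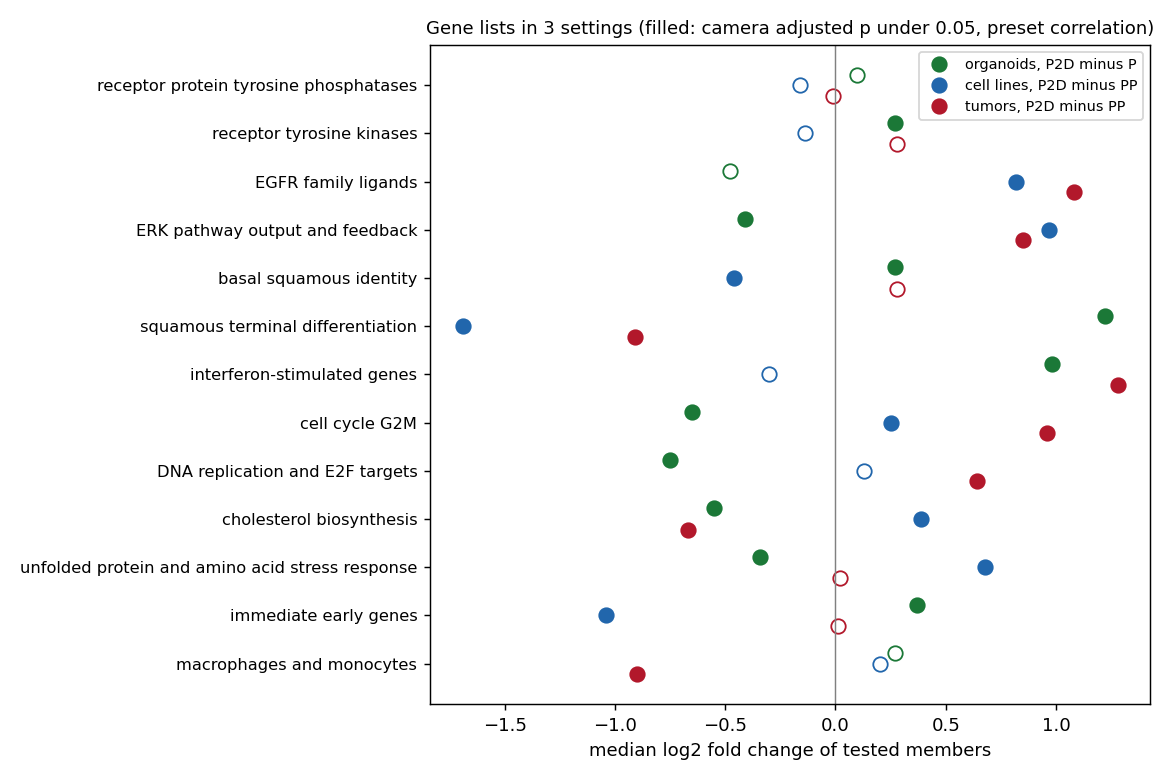
Median log2 fold change of tested members of 13 gene lists in organoids (P2D minus P), cell lines and tumors (P2D minus PP), with filled points for lists called by camera with the preset correlation. The squamous terminal differentiation list lies at 1.22 in organoids, -1.69 in cell lines and -0.91 in tumors.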

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

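The tests of chromosome-centred squamous genes, of the Pten reference and of the Y-linked genes were chosen after the result was seen. The difference between the P2D effect in tumors and in cell lines was tested in a joint fit with 1 spread per gene over both. It passed for 496 genes with a higher and 278 with a lower effect in tumors. Since each genotype had 1 cell line, these differences compare the tumors with single lines.

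Log2 differences, tumor effect minus cell line effect, were largest among the genes named by the rule for Pdgfrb (11.55), Igfbp2 (10.16), Col1a2 (10.05), Postn (9.51) and Krt79 (8.89) in one direction. In the other they were largest for Bcat1 (-8.17), S100a8 (-6.47), Itga2 (-6.13), Myl7 (-5.99) and Cd53 (-5.81). The fitted values for Pdgfrb, Col1a2 and Postn rest on 0 to 2 counts in the P2D line and depend on the prior count. S100a8 and Cd53 were too low to be tested within the cell lines. Krt79, Bcat1 and Cd53 lost their call whichever 1 of the 4 cell line libraries was left out, and Itga2 lost it when either PP line library was. Bcat1 was also not called without PP tumor replicate 2, and Cd53 without P2D tumor replicate 3.

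Among other genes in the text, the effect was higher in tumors for the matrix genes Col5a1 (8.66), Col1a1 (8.18), Fstl1 (6.19) and Igfbp5 (4.94), and for Ctnnd2 (4.31). It was higher for the signalling genes Epgn (6.58), Ptpru (5.76), Egr1 (3.34), Fgfr2 (2.94), Wnt11 (2.70), Jun (2.57), Etv4 (2.12) and Ptprz1 (1.26). The same held for Sostdc1 (5.98), Car12 (5.99), Tanc2 (3.67), Nlrp10 (3.54), Aldh3a1 (3.36), Rgma (3.34), Sncg (3.05) and Cdc20 (1.26), for the squamous genes Dsc3 (3.80) and Calml3 (1.90), and for the Y-linked genes Ddx3y (6.36), Eif2s3y (6.27), Uty (6.03) and Kdm5d (5.14). The effect was lower in tumors for Cxcl5 (-5.36), Il1a (-4.84), Sema7a (-4.64), Plac8 (-4.57), Stc2 (-3.14), Sprr2a1 (-3.14), Fosl1 (-2.75), Ptprg (-2.08), Msmo1 (-1.82), Mvd (-1.72) and Phlda1 (-1.45). Tumor libraries cover all cells of the tumor. The matrix gene Col1a2 was at 101 and 135 CPM in P2D and PP tumors and at 0.0126 CPM in the P2D line. Which tumor cells gave such transcripts was not tested, so the matrix and Y-linked differences need not lie within the squamous cells.

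As lists, with the preset correlation, the effect was higher in tumors for sex-chromosome genes (median difference 6.03), fibroblasts (1.84), mesenchymal genes (1.16), immediate early genes (1.02), the hedgehog pathway (0.94), basal squamous identity (0.81), G2M (0.68) and DNA replication (0.64). It was lower for neutrophils (-1.76), cholesterol synthesis (-1.12), macrophages (-0.68), the unfolded protein and amino acid stress list (-0.68), hypoxia and glycolysis (-0.54) and inflammatory cytokines (-0.53). Fewer than 3 neutrophil genes were expressed in the cell lines, so that difference sets the tumor change against fitted values on near-zero counts. None of these lists was called with an estimated correlation, where the smallest adjusted p was 0.659. The squamous terminal differentiation list did not differ by this test (adjusted p = 0.71). Which tumor cells gave the fibroblast, mesenchymal and Y-linked transcripts was not tested, so those differences need not lie within the squamous cells.

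Expression in the P2D line was shifted by chromosome, with medians beyond 0.2 log2 and outside random gene lists on 7 autosomes. Clustered loci are argued against for chromosomes 8 and 15, where 0 of the 10 segments lay on the other side of 0. The other autosomes were not divided into segments. A bias of low-count genes is argued against too. Of the 15 autosomes with a median beyond 0.1, 13 (86.7%) kept their sign and at least 0.5 of the size among higher-expressed genes. Unequal chromosome copy number between the cell lines is a candidate explanation, and no DNA was measured here. In tumors 15 autosomes were outside random lists, with chromosomes 8 and 15 shifted in the direction of the line (-0.299 and 0.281) but chromosomes 7, 12 and 19 at 0.344, -0.319 and -0.376 against 0.023, 0.122 and -0.112 in the line, and their cause was not tested. An effect of Kmt2d on whole chromosomes stays open as untested, though 0 of the organoid autosomes were outside random lists.

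The squamous terminal differentiation list was higher in P2D organoids and lower in the P2D line and tumors, by calls that were lost with an estimated correlation (adjusted p = 0.447, 0.425 and 0.745), and the difference between organoids and the other settings was not tested. Median shifts of whole chromosomes are too small to account for it in the cell lines. The largest on an autosome was -0.417 (chromosome 8), against a list median of -1.69. Centring on chromosomes could therefore not move the list's median far, and left it at -1.71. Shifts of parts of a chromosome were not covered. In tumors the list's median was -1.68 with a leukocyte covariate and -0.91 without. A different share of leukocytes stays open, since the covariate did not remove the difference in leukocyte genes. With it the median was -1.51 for neutrophil genes (-1.89 without) and -0.7 for macrophage genes (-0.9 without). For T and NK cell genes it was 1.76 with the covariate and 0.16 without. Pten deletion in the reference of the lines and tumors may contribute and cannot be told apart from the setting, as 0 organoid libraries were labelled with it. No biological explanation was tested.

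Of 5 tested Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty were at most at 0.188% of their PP level in the P2D line, while the pseudogene Mid1-ps1, chosen after its values were seen, was at 102%. Absence of the Y chromosome from that line asked for every tested Y-linked gene at 2% or less, so it stays open, and the source of the Mid1-ps1 reads was not tested. Female cells that express Xist are argued against, since Xist was at most at 0.0271 CPM there. Female cells without Xist are not covered by this. In P2D tumors the 4 genes were at 6.36% to 8.96% of their PP level and Mid1-ps1 at 165%, and whether the remainder came from other cells of the tumor was not tested. In organoids they were at 109% to 129% of the P level and Mid1-ps1 at 78.8%.

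The 6 tumors can be split in 10 ways into groups of 3, which is too few for a share under 0.05. The genotypes gave 257 changed genes and the highest other split 0, so 1 split gave as many genes. For gene lists, the genotypes gave 16 and the highest other split 26, and 8 of the splits gave as many.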

How the results depend on the processing

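The alveolar covariate and the centring on chromosomes were chosen after seeing the data. The other alternatives were planned, and the replicate block for the cell lines was planned but not run. No paired analysis of the cell lines was possible because both of their P2D columns carry the same replicate number. In organoids and tumors replicate number was fitted as a block, though it did not pair the libraries. For libraries with the same number, correlations of deviations from the group means were -0.002 in organoids and -0.009, -0.272 and -0.012 in tumors. With different numbers they were 0.002 in organoids and ran from -0.19 to 0.23 in tumors. With 2 libraries per group, the organoid values can differ in sign only. Groups of 2 or 3 libraries were too small to test for a library far from the others.

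In organoids and cell lines the counts of changed genes stayed within 1.5 times under the other scalings, filters, tests, rounding and the 0.01 threshold. By construction they fell with a 2-fold threshold, to 650 and 550 in organoids and 1102 and 1906 in cell lines, and with 1 fit over all settings, which pools the spread with the tumors, to 100 and 81 in organoids and 1237 and 1392 in cell lines. Without 1 library at a time the counts were 2489 to 3236 higher and 2720 to 3552 lower in organoids, and 4544 to 5089 and 4574 to 5192 in cell lines. Of the 70 organoid genes in the text that were called, 44 kept their call at 2-fold and 22 in the joint fit, and of the 63 called cell line genes 54 and 57 did. Organoid Pten was at 0 log2 with library size only and between -0.07 and 0.10 without 1 library. With replicate number as a block, the organoid counts were within 1.5 times and 69 of the 70 called genes kept their call. Kmt2d in cell lines, not called as reported, was called higher by DESeq2 (adjusted p = 0.0182), by limma voom (0.000536) and without the robust option (0.000313), and the cause was not tested. Its log2 change was 0.84 without P2D library a and 0.43 without P2D library b, in fits that leave 1 P2D library. Mid1-ps1 in cell lines was at -0.06 log2 with library size only and with the upper quartile, and between -0.10 and 0.16 without 1 library, and the cause was not tested. Library size alone moved the median of all genes in the cell lines to -0.106 log2, and 41.1% of calls were then higher against 49.9%.

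Tumor counts depended on more settings, and apart from stricter thresholds, pooled spread and fewer samples the cause was not tested. They were 288 and 368 without a filter, 587 and 736 by DESeq2, 7 and 27 at an adjusted p under 0.01, and 1594 and 1634 in 1 fit over all settings. The lower count was 109 with replicate number as a block. With the alveolar covariate the counts were 22 and 53, and centred on chromosomes 39 and 98. Without 1 library the counts ran from 10 to 76 higher and from 37 to 116 lower. Of the 42 tumor genes in the text that were called, 30 kept their call with the block, 29 with the leukocyte covariate, 23 with the alveolar covariate and 30 when centred on chromosomes.

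Some tumor genes that passed no test changed sign, and the cause was not tested. Tgfa was at 0.05 with library size only and 0.03 with the alveolar covariate. Irf7 was at -0.04 with the upper quartile, -0.01 with the stricter filter, -0.63 with limma voom, -0.01 in 1 fit over all settings, -0.68 with the block and -0.33 centred on chromosomes. With the leukocyte covariate Trp53 was at 0.27 and Hbegf at -0.09. Without 1 library, Trp53 ran from -0.33 to 0.08, Pten from -0.05 to 0.18, Hbegf from -0.22 to 0.54, Tgfa from -0.41 to 0.28, Krt14 from -0.49 to 0.14, Irf7 from -1.48 to 0.48 and Stat1 from -0.39 to 1.76.

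With an estimated correlation between genes, 0 lists were called up and 0 down in organoids, cell lines and tumors, against 16 in each with the preset correlation, and the cause was not tested. A correlation above the preset 0.01 does not account for all of these losses. In the cell lines the estimate was 0.005 for squamous differentiation, 0.002 for G2M and -0.005 for mesenchymal genes, and these calls were lost too. A call lost with the estimated correlation therefore does not by itself show that the list's genes varied together. Other called lists had larger estimates, such as 0.503 for mitochondrially encoded genes in the cell lines. With the estimated correlation, adjusted p were 0.766 for receptor tyrosine kinases and ERK output, 0.749 for basal identity and 0.447 for squamous differentiation in organoids. In cell lines they were 0.638 for EGFR ligands, 0.425 for ERK output, 0.502 for basal identity and 0.425 for squamous differentiation. In tumors they were 0.613 for EGFR ligands, 0.536 for ERK output and 0.745 for squamous differentiation. By fry, which tests each list without comparing it with other genes, 14 lists were up and 12 down in organoids, 19 up and 12 down in cell lines, and 0 were up and 0 down in tumors. Its adjusted p were 0.0356 for receptor phosphatases and 0.0102 for EGFR ligands in organoids, 0.591 in the other direction for receptor phosphatases in cell lines, and 0.147, 0.0595 and 0.344 for EGFR ligands, ERK output and squamous differentiation in tumors. On ranks they were 0.0628 for ERK output in organoids, 0.0755 for EGFR ligands and 0.08 for inflammatory cytokines in cell lines, and 0.984 in the other direction for receptor phosphatases in tumors. With the block, receptor tyrosine kinases in organoids had 0.0633.

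Without 1 library, the adjusted p ran from 0.0091 to 0.14 for receptor tyrosine kinases in organoids. In tumors it ran from 0.647 to 0.968 for receptor phosphatases, with the direction changing, from 0.0159 to 0.708 for receptor tyrosine kinases, from 0.0195 to 0.986 for basal identity and from 0.000151 to 0.23 for interferon-stimulated genes. From 5 to 10 tumor lists were called up. Squamous differentiation and ERK output kept their calls in every such fit of the tumors, with adjusted p up to 0.000752 and 3.37e-05. Such fits leave 1 library in a group of organoids or cell lines, so they cannot show stability there. The difference between tumors and cell lines ran from 152 to 752 genes higher and from 60 to 482 lower.

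The sizes of the overlaps moved with the number of called genes at a 2-fold threshold and with DESeq2 calls. Their ratio to independent calls moved too, and the cause was not tested: for organoids and cell lines it went from 0.947 to 1.63 at 2-fold for both higher and from 0.937 to 2.45 for both lower. At 2-fold, organoids and cell lines shared 59 (both higher), 195 (higher, lower), 110 (lower, higher) and 99 (both lower). Organoids and tumors shared 2, 8, 7 and 11 in the same order, and 101, 150, 235 and 108 with DESeq2 calls. Cell lines and tumors shared 29, 3, 9 and 56, and 358, 60, 80 and 360 with DESeq2 calls. Depth limited few named genes: Cntn2, Postn, Col1a2, Htra4, Uty and Pdgfrb had 0 to 2 counts in the P2D line, where a count of 0 was set against a floor of 3.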

Other observations

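The genes in this part were chosen after the result was seen. Of 13309 genes tested in organoids, cell lines and tumors, 111 were called in all of them and 39 of these in the same direction, 15 higher and 24 lower in P2D. The number that independent calls would give was not computed, and 50.2% of tested organoid genes were called. Organoids and tumors shared 27 rises where 22.8 were expected and 36 falls where 29.6 were (hypergeometric adjusted p = 0.31 and 0.204). At 2-fold, shared falls were 11 where 3.7 were expected. The 39 genes therefore do not by themselves show a shared response. Gpx2, a glutathione peroxidase gene, changed by -1.12, -0.74 and -1.33 log2 in organoids, cell lines and tumors. Plat, which encodes tissue plasminogen activator, changed by -1.02, -1.93 and -3.30. The homeobox gene Irx2 changed by 0.15, 1.06 and 2.52. Its organoid call (adjusted p = 0.0464) was lost with library size only (0.114), the upper quartile (0.0538), no filter (0.148), DESeq2 (0.066) and the fit without the robust option (0.0529), and without any 1 of the 4 libraries (0.114 to 0.171). The tumor call of Gpx2 was lost without any 1 of the 6 libraries (0.0646 to 0.106), and that of Plat without PP replicate 2 (0.0507), P2D replicate 1 (0.0699) or P2D replicate 3 (0.0642). That of Gpx2 was also lost with replicate number as a block (0.0808), the leukocyte covariate (0.0773), the alveolar covariate (0.0801) and centring on chromosomes (0.079). The tumor call of Irx2 was lost without any 1 PP library (0.0641 to 0.0849). Its organoid call was also lost with replicate number as a block (0.104) and with centring on chromosomes (0.104).

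Xist differed between tumors within a genotype. It was at 0.0955, 107 and 1.39 CPM in PP tumors 1 to 3 and at 0.116, 1.86 and 8.64 CPM in P2D tumors 1 to 3. P2D tumor 2 stood apart on the second principal component, at 63.3 against -56.4 and -35.6 for the other P2D tumors.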
